A study of Mus musculus with 6 samples.

How the data were processed

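RNA was measured in 6 samples of KIT-positive cells sorted from mouse testis at postnatal day 8, 3 WT and 3 cKO. Per the labels' protocols, polyadenylated RNA was amplified full length by a Smart-seq2 method and made into libraries with a transposase kit that does not mark strand. The submitters' processing notes name cutadapt 1.18, STAR 2.7.10a, SAMtools 1.9, featureCounts 1.6.0, DESeq2 1.20.0 and the mm10 build, with no roles. Counting options, and where the PROMPT, ptRNA and repeat intervals came from, are not given in the sources used here.

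The authors deposited 1 table of 89597 rows, 1 line of which was emptied for this work. Per the file headers, it holds a normalized signal for each library (counts divided by 1 size factor per library) and the authors' mean over the 6 libraries, together with the authors' log2 fold change and its standard error, the authors' Wald score, and the authors' p-value and adjusted p-value. The size factors came from all rows of the table, which are mostly repeats: factors recomputed as medians of ratios over all rows differed from the deposited ones by at most 0.00147%. Values are whole multiples of 1 step per library within 0.001 reads (relative above 1000 reads) in 100.0% of rows, and the smallest value is 2 reads in every library, so RNAs at 0 or 1 reads in any library were not analysed here. Counted up over all rows, these steps came to 29893103, 27399089 and 20697972 reads for WT replicates 1 to 3. For cKO replicates 1 to 3 they came to 28542329, 30270560 and 29341181, and size factors ran from 0.666 to 1.379. These sums are not library sizes, since rows overlap: 2396 ptRNA hosts are also gene rows, so a read may be counted again. Reads are not molecules, so depth sets only a counting error.

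Samples were grouped by title. WT replicate 3 has a genotype tag that names the knockout and was kept as WT, and each main count was also made without it. Pairs of replicates differed beyond sampling noise, with a chi-square per gene of 17.5 to 47.8, so none was counted as a duplicate. Replicate 3 of both groups carries a code in its label that the others lack, which was treated as a possible batch with 1 library per group, by leaving both out and by a term in the fit. Gene rows were named by Ensembl ID from GENCODE M21 (mm10), which matched 18155 of 18168.

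A count test was planned, with limma-trend on log2(value + 1) if the table held normalized values. As it did, limma 3.58.1 in R 4.3.3 was the test, on the deposited scaling, for each feature type on its own, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Rose and fell mean passing that test. Fold changes are on the log2(value + 1) scale and understate the change of low RNAs. No further filter on low values was used. PROMPTs, ptRNAs, hosts and repeats, and their ratios to host or gene, were added after the table was opened. On simulated genes, the test recovered 17.9% of 1.5-fold, 58.2% of 2-fold and 97.0% of 4-fold changes among 17869 genes, with 4 false calls. Only 200 genes were changed there, a far smaller share than was called in the data, so power in the data may differ.

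The 23 gene lists were fixed before the data were examined (518 genes measured, 15 in more than 1 list) and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The lists are nuclear exosome subunits, MTR4 partners, undifferentiated and differentiating spermatogonia, meiosis, spermatids, Sertoli, Leydig, myoid and mesenchymal, endothelial, macrophage, mast and erythroid markers, p53 targets, interferon-stimulated genes, snoRNA hosts, ribosome biogenesis, retinoic acid, mitotic cycle, piRNA pathway, cholesterol biosynthesis, immediate early and heat shock genes, and apoptosis and stress response. Gene classes came from the annotation's biotypes, and histone and ribosomal protein genes from symbols. Class shares were compared by exact permutation. Annotated terms were not used here.

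Genes were named by a rule fixed before the data were examined: Mtrex; of the genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 12 largest rises and 12 largest falls with approved symbols and 4 each of the rest; of each list the up to 4 members past the threshold with the smallest adjusted p, or, where none passed, the 2 with the highest mean; and 8 genes of spermatogonia and meiosis. Of 109 such genes 23 rose, 73 fell and 13 did not pass; all 23 rises and 25 of the falls held with gene-row median scaling. Other names were chosen after their values were seen. Alternatives were other scalings, limma-voom (on values divided by the step), filters, pseudocount 0.1, thresholds, a replicate block, a term for replicate 3 and each library left out in turn. Locations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.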

Results

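MTR4, encoded by Mtrex, is an RNA helicase that hands nuclear RNAs to the exosome for decay. RNA-seq was performed on KIT-positive cells sorted from the testes of mice at postnatal day 8, to ask which RNAs MTR4 regulates in differentiating spermatogonia. There were 3 libraries from wild-type (WT) mice and 3 from conditional knockout (cKO) mice. Counts summed to 15109413 to 21897757 reads per library over 18168 gene rows. Over all rows of the table they summed to 20697972 to 30270560, but rows overlap and may share reads. The table also listed 4489 promoter upstream transcripts (PROMPTs), 1119 ptRNAs (in this field, prematurely terminated RNAs), 2420 rows of ptRNA host genes and 63401 repeats. Levels are size-factor normalized counts, given as mean ± SD over 3 libraries per group. The labels do not say whether the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

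Mtrex itself fell to 0.128 of its WT level. It stood at 4110 ± 1220 normalized counts in WT and 518 ± 104 in cKO (n = 3 each), a log2 change of -2.97 (SE 0.24, limma adjusted p = 8.79e-06). Mtrex (ENSMUSG00000016018.4) lies on the minus strand of chromosome 13, from 112867418 to 112927398 (mm10). Kit, the receptor used for sorting, also fell, from 4160 ± 266 to 1790 ± 196 normalized counts (log2 change -1.22, SE 0.18, limma adjusted p = 0.000746). WT replicate 3 is WT by its title although its genotype tag names the knockout, and its Mtrex level of 3562 normalized counts was near those of WT replicates 1 (5508) and 2 (3248) and above the cKO levels of 585, 571 and 398.

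**Figure D1:**
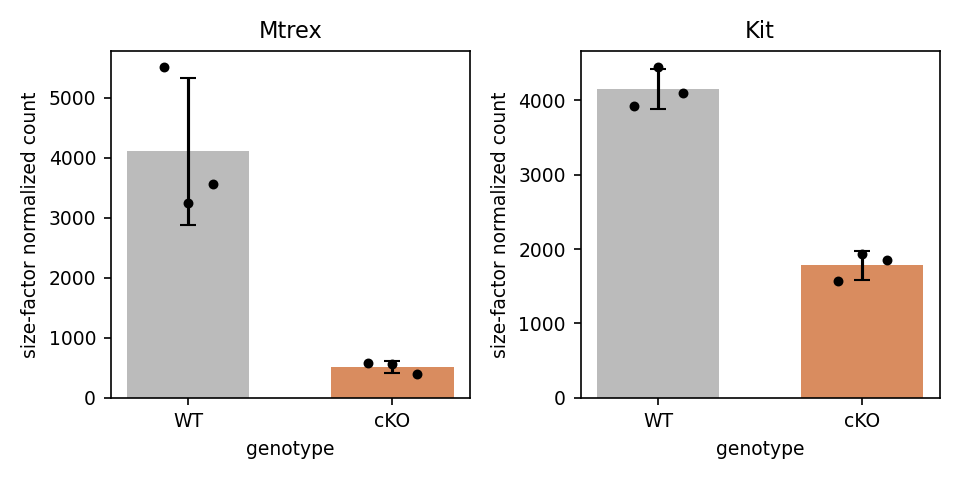
Size-factor normalized counts of Mtrex (left) and Kit (right) in WT and cKO libraries. Bars are means, error bars are SD and points are the 3 libraries of each group. Every cKO library lies below every WT library for both genes.

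Many histone, small nuclear and long noncoding RNA genes rose in the knockout. Polyadenylated RNA was amplified, so these are levels of the captured forms, and a change in polyadenylation and a change in abundance were not told apart. Of 52 replication-dependent histone cluster genes, whose mRNAs end in a stem-loop and not a poly(A) tail, 46 rose and none fell, with a median 7.55-fold change. Hist1h4i rose from 254 ± 11.8 to 7380 ± 1260 normalized counts (log2 change 4.84, SE 0.19, limma adjusted p = 3.46e-08). Hist1h2bp, Hist1h1d, Hist1h4m and Hist4h4 rose by 5.18, 5.10, 4.60 and 4.45 on the log2 scale, and the pseudogene Hist3h2bb-ps by 4.57. Of 25 snRNA genes, 18 rose and none fell, with a median log2 change of 3.55. Among them Gm25939 rose from 3.14 ± 1.16 to 1110 ± 465 normalized counts, Gm25360 from 29.8 ± 10.7 to 7730 ± 3610, Gm23971 from 4.96 ± 2.25 to 585 ± 295, and Rnu2-10, a U2 gene, from 37.5 ± 21 to 1000 ± 440.

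Of 1782 long noncoding RNA genes, 548 rose and 31 fell. The shares that rose were 59.2% of 125 bidirectional promoter transcripts, 36.8% of 611 antisense genes and 22.0% of 658 lincRNAs. The lincRNA Platr23 rose by 4.81 on the log2 scale (SE 0.39, limma adjusted p = 9.76e-06), and 2310043P16Rik, 1 of 133 genes of the TEC class (to be experimentally tested) that rose, by 6.88 (SE 0.46). Of 41 snoRNA and scaRNA genes, 12 rose, led by Snord13 at 5.30 (SE 0.46), and 8 of 28 microRNA genes rose. The Y RNA Rny1 rose by 4.59 (SE 0.43). Histone cluster genes made up 0.0185% ± 0.00182 of gene reads in WT and 0.192% ± 0.0122 in cKO (n = 3 each, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The snRNA share went from 0.00261% ± 0.000199 to 0.138% ± 0.0422 and the long noncoding share from 0.833% ± 0.0817 to 1.9% ± 0.279 (n = 3 each, exact permutation p = 0.1 for both). In a logistic model with expression level and exon length, the log2 odds of rising were -0.40 for snoRNA and scaRNA genes and -0.45 for microRNA genes, so their excess of rises was lost. Copies of histone and snRNA genes are near-identical, and antisense genes overlap others without strand being marked, so levels of single genes in these classes are uncertain.

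**Figure D2:**
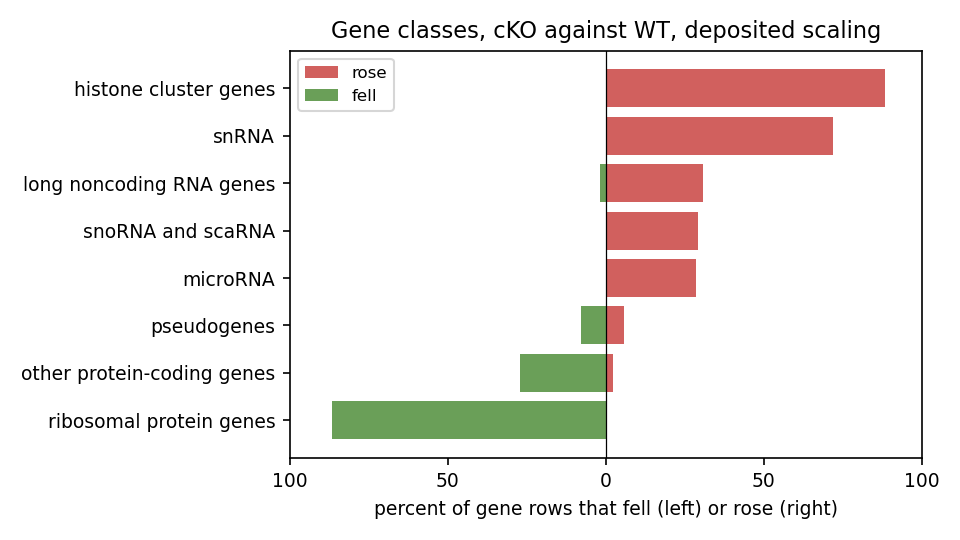
Percent of the gene rows of each class that rose (right) or fell (left) in cKO at a limma adjusted p of 0.05 with the deposited scaling. Histone cluster genes rose in 88.5% and snRNA genes in 72.0% of rows. With gene-row median scaling only 1 of the 72 ribosomal protein genes that fell, and 248 of the 14519 other protein-coding genes, passed as falls.

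Over all genes, 1172 rose and 4045 fell with the deposited scaling, so that 22.5% of calls were rises. Scaling by the median of the gene rows shifted the median of all genes up by 0.41 on the log2 scale and gave 1393 rises and 250 falls, with 84.8% of calls rises. Of these, 1162 genes rose and 250 fell under both scalings, and none changed direction. Log2 changes of genes are those of the deposited scaling unless another is named, and a call under both scalings passed in each with its own size. The fall of Mtrex was joined by Stc1, which encodes the secreted hormone stanniocalcin (827 ± 417 to 141 ± 78.9 normalized counts, log2 change -2.59), Fmo5 (-2.14), the tight junction gene Cldn1 (-1.89), Mfap3l (-1.87) and Acsbg1, which activates fatty acids (3660 ± 1250 to 1080 ± 541, -1.82), all of which fell under both scalings. Serpina3g, Paqr5, Gabra4, Itih2, Serpina3c and Naalad2 fell by 1.84 to 2.41 with the deposited scaling alone, as did Gm15427, Gm13456, 2210408F21Rik and Gm6136. Among protein-coding genes other than histones, 331 rose, led by Prr15l (7.59 ± 5.70 to 278 ± 49.3 normalized counts) and Zbtb12 (7.66 ± 4.22 to 270 ± 66.6). The number of falls was 986 without WT replicate 2, 2137 without WT replicate 3, 1897 without cKO replicate 2 and 2258 without cKO replicate 3. Replicate 3 of both groups has a code in its label that the others lack; without both, 971 genes rose and 1185 fell, and with a term for replicate 3, 1371 rose and 5222 fell. The authors' deposited table marked 1145 genes as up and 2805 as down, of which 1097 and 2649 were also called here, with 0 in the opposite direction. The authors' calls came from a Wald test and those here from limma within each feature type, so counts need not match in any type.

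Of 16 measured genes of differentiating spermatogonia 9 fell (9 also when adjusted over the list alone), and 3 fell with gene-row median scaling, namely Dnmt3b, a DNA methyltransferase (log2 change -1.28), Kit (-1.22), the gene sorted on, and the cyclin Ccnd1 (-1.38). Sohlh2, a transcription factor of this stage, fell by 0.79 with the deposited scaling alone. Of 62 meiotic genes, 3 rose and 10 fell (2 and 6 when adjusted over the list alone), while with gene-row median scaling 9 rose and 1 fell. Spo11, which makes meiotic DNA breaks, rose from 86.4 ± 8.75 to 224 ± 60.1 normalized counts (log2 change 1.33, SE 0.33, limma adjusted p = 0.0122) under both scalings, and Hspa2 fell by 1.12 with the deposited scaling and passed as a fall under both (log2 change -0.71 with gene-row median scaling). Mei4 (-0.95) and Zcwpw1 (-0.77) fell with the deposited scaling alone. The meiotic entry genes Stra8, Gm4969 (Meiosin) and Rec8 had log2 changes of -0.36 (SE 0.22), 0.21 (SE 0.41) and -0.10 (SE 0.42), with limma adjusted p of 0.229, 0.715 and 0.873. Sycp3 (-0.19, SE 0.30) and Dmc1 (0.06, SE 0.27) did not pass either. Of 25 genes of undifferentiated spermatogonia 1 rose (Neurog3, 1.25) and 1 fell (Cdh1, -1.57, deposited scaling alone), the same counts as over the list alone, and Gfra1 (-0.45, SE 0.37) and Zbtb16 (-0.55, SE 0.27) did not pass. Of 19 spermatid genes Tssk6 and Tssk3 rose under both scalings and Crem fell with the deposited one (1 and 0 over the list alone). Of 20 retinoic acid pathway genes 11 fell (11 over the list alone), and Rdh11 (-1.27) and Aldh1a2 (-1.28) did so under both scalings.

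Falls with the deposited scaling took in 22.3% of all genes and 27% of protein-coding genes other than histones. They were many in the cholesterol, mitotic cell cycle, ribosome biogenesis and piRNA lists, whose expression levels were not matched to other genes. In cholesterol biosynthesis 20 of 22 members fell (21 when adjusted over the list alone, 7 with gene-row median scaling), among them Mvd (-1.40, SE 0.18, limma adjusted p = 0.000295), Sqle (-1.35), Hmgcs1 (-1.33) and Lss (-1.26), all under both scalings. Of 40 mitotic cell cycle genes 30 fell (33 over the list alone, 5 with gene-row median scaling), including the replication genes Mcm2 (-1.12) and Mcm7 (-1.07), Kif20a (-1.09) and Ccne1 (-1.12). In ribosome biogenesis 45 of 70 fell (56 over the list alone, 3 with gene-row median scaling, 1 rising there), with Nop9 (-1.09), Bop1 (-1.10) and Nat10 (-1.07) under both. Of 23 piRNA pathway genes, which silence transposons, 12 fell (16 over the list alone) and none with gene-row median scaling, Mov10l1 (-0.94) and Piwil2 (-0.87) among the 12.

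The RNA decay machinery and stress lists held few rises with either scaling, and more falls than rises with the deposited scaling alone. Of 12 nuclear exosome subunits 2 fell (2 over the list alone), Dis3 (-0.91) and Exosc10 (-0.73), and of 19 MTR4 partner genes 5 fell (2 rises and 9 falls over the list alone), among them Ncbp1 (-0.95), none of these falls with gene-row median scaling. With that scaling 2 MTR4 partner genes rose (3 over the list alone). Of 26 snoRNA host genes 3 rose and 7 fell (3 and 8 over the list alone), with Snhg20 up by 0.84 with the deposited and 1.25 with gene-row median scaling. In the latter scaling 4 snoRNA host genes rose and none fell. Of 31 p53 targets 1 rose, Gdf15 (1.92, both scalings), and 11 fell (2 and 15 over the list alone), Ei24 (-0.99) under both scalings. With gene-row median scaling 2 p53 targets rose and 1 fell. Falls were 4 of 19 apoptosis and stress response genes (4 over the list alone), 2 of 23 immediate early and heat shock genes and 2 of 24 interferon-stimulated genes (0 over the list alone for both), with no rise in these lists.

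Markers of other cells that the sort may have let through moved in several directions. Leydig cell markers fell in 4 of 10 (6 over the list alone), with Lhcgr at 604 ± 251 and 198 ± 219 normalized counts, Sertoli markers in 4 of 24 (3 over the list alone) and endothelial markers in 1 of 9 (Egfl7, also over the list alone). With gene-row median scaling only Fabp5 among them still fell. None of 14 macrophage and none of 15 myoid and mesenchymal markers passed, with Lyz2 at 10200 ± 5710 and 7730 ± 4210 and Col1a2 at 1880 ± 1620 and 2450 ± 1910, and none passed over the list alone. Of 6 mast cell markers Mcpt4 rose (log2 change 2.68, 1 also over the list alone), from 60.1 ± 59.5 to 265 ± 135. Of 5 erythroid markers none passed (0 over the list alone), but all 5 rose over the list alone with gene-row median scaling. Hba-a1 stood at 1290 ± 1830 and 4000 ± 4560, with 3401 in WT replicate 1 and 9207 in cKO replicate 1 against 123 to 351 and 726 to 2063 in the others. Lyz2 was highest in replicate 3 of both groups (16600 and 12574, against at most 8210 and 5606), and Lhcgr stood at 451 in cKO replicate 3 against 65.3 and 78.8 in the other cKO libraries.

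Set against all other genes by camera with a preset correlation, 5 of the 23 lists moved down, namely ribosome biogenesis (adjusted p = 4.41e-07), mitotic cell cycle and cholesterol biosynthesis (adjusted p = 8.83e-07 for each), piRNA pathway (adjusted p = 0.00893) and differentiating spermatogonia (adjusted p = 0.0161). The mast cell list (adjusted p = 0.0244) and the erythroid list (adjusted p = 0.00376) moved up. With an estimated correlation none of these calls held, the adjusted p being 0.574 for the piRNA list and 0.525 for the other 6. With at most 6 libraries that form of camera has little power in every setting given here. The p53 targets, which did not pass with the preset correlation (camera adjusted p = 0.248), also stood at 0.525. The failures of that form therefore do not decide whether a list moved. Nor do the passes with the preset correlation of 0.01. The estimated correlation of these 7 lists ran from 0.17 (differentiating spermatogonia) to 0.98 (erythroid), so the preset p-values may be too small. With gene-row median scaling the meiotic list passed as up (camera adjusted p = 0.0357, against 0.213 with the deposited scaling), and the Leydig and retinoic acid lists as down (adjusted p = 0.0357 for each, against 0.132 and 0.0871), while the mast cell list did not pass (adjusted p = 0.109). With an estimated correlation in that scaling none passed, the adjusted p being 0.916 for the meiotic list and 0.634 for the Leydig and retinoic acid lists. Without replicate 3 of both groups, the calls of differentiating spermatogonia (camera adjusted p = 0.141), the piRNA pathway (adjusted p = 0.0668) and mast cells (adjusted p = 0.594) were lost. The meiotic list then passed as up (adjusted p = 0.00121), and the Leydig (adjusted p = 0.000111), endothelial and retinoic acid lists (adjusted p = 0.00959 for each) as down. With a term for replicate 3 the Leydig list alone was gained (adjusted p = 0.0166) and no call was lost. With an estimated correlation no list passed in either setting, the smallest adjusted p being 0.653 without replicate 3 and 0.614 with the term. For the other 16 lists the camera adjusted p ran from 0.0871 (retinoic acid) to 0.887 (Sertoli and macrophage). The camera direction was up, against a negative median log2 change, for the meiotic, spermatid, macrophage, interferon-stimulated, snoRNA host and immediate early lists. Lists up numbered 1 without WT replicate 3, and lists down 8 without cKO replicate 3, where none passed with an estimated correlation (smallest adjusted p = 0.447). Leaving out cKO replicate 3 alone lost the mast cell call (camera adjusted p = 0.171). The meiotic (camera adjusted p = 0.00185) and myoid lists (adjusted p = 0.00796) then passed as up. The Leydig (adjusted p = 0.000525), retinoic acid (adjusted p = 0.0232) and macrophage lists (adjusted p = 0.0341) then passed as down. Of the 10 splits of the 6 libraries into groups of 3, 7 gave at least 7 lists, and the highest other split gave 15.

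PROMPTs, short-lived transcripts from upstream of promoters, rose broadly. Of 4489 PROMPTs 3098 rose and 31 fell, with a median log2 change of 1.9 (3.73-fold), and with gene-row median scaling 3488 rose and 6 fell. Against the gene downstream, a ratio in which library scaling largely cancels, 3344 of 4260 rose and 14 fell, with a median 5.47-fold change. PROMPT reads per 1000 gene reads were 14.8 ± 0.369 in WT and 80.5 ± 7.69 in cKO (n = 3 each, exact permutation p = 0.1, two-sided). Those of Hnrnpa0 and Uimc1, chosen after their values were seen, rose from 19.8 ± 1.9 to 2250 ± 461 normalized counts (log2 change 6.75, SE 0.30, limma adjusted p = 6.17e-10) and from 28.4 ± 10.8 to 4870 ± 2170 (7.32, SE 0.38, limma adjusted p = 1.66e-09). Without cKO replicate 2, 17 PROMPTs fell and 3 fell against the gene, and without cKO replicate 1, 6 fell against the gene. The library kit does not mark strand and the counting options are not given in the sources used here, so a PROMPT and an overlapping gene cannot be told apart by strand. The origin of the PROMPT and ptRNA intervals is not given either. Whether they were chosen from reads of these libraries, which could favour rises, stays open.

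The ptRNAs rose with them. Of 1119 ptRNAs 564 rose and 12 fell, with a median log2 change of 1.25 (2.39-fold), and with gene-row median scaling 725 rose and 3 fell. Relative to the host, 629 of 941 rose and 3 fell, with a median 3.66-fold change. The ptRNAs of Unk and of Huwe1, an E3 ubiquitin ligase gene, chosen after their values were seen, rose from 22.4 ± 13.6 to 1170 ± 221 normalized counts (log2 change 5.78, SE 0.40, limma adjusted p = 7.55e-09) and from 13.1 ± 7.63 to 474 ± 109 (5.26, SE 0.48, limma adjusted p = 1.05e-07). Of 2420 host rows 39 rose and 968 fell, but with gene-row median scaling 31 rose and 12 fell, and the falls were 487 without WT replicate 2, 639 without cKO replicate 2 and 547 without cKO replicate 3. The ptRNAs that fell numbered 5 without WT replicate 2, 6 without WT replicate 3, 4 without cKO replicate 1 and 6 without cKO replicate 2, without which 21 hosts rose and 1 ptRNA fell against its host. The authors' deposited table marked 2939 PROMPTs, 526 ptRNAs and 30 hosts as up and 12, 7 and 549 as down.

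**Figure D3:**
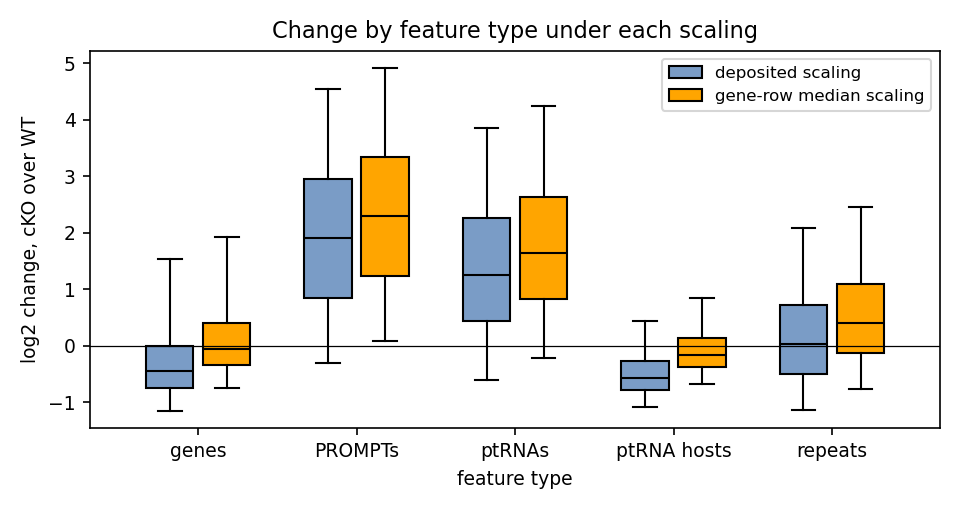
Log2 change of cKO over WT for each feature type, with the deposited scaling (blue) and with gene-row median scaling (orange). Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles. The PROMPT median lies at 1.9 and 2.30, the ptRNA median at 1.25 and 1.64, and the gene median at -0.45 and -0.05.

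Repeats rose in smaller proportion than PROMPTs and ptRNAs, but their levels were lower, so fewer may pass. The median normalized count was 18.3 for repeats, 84.5 for PROMPTs and 45.5 for ptRNAs. Of 63401 repeat rows 4650 rose and 458 fell, and with gene-row median scaling 8016 rose and 98 fell. The median log2 change of 0.03 is held near 0 by the deposited scaling, which was taken from rows that are mostly repeats. Repeat reads per 1000 gene reads were 184 ± 4.28 in WT and 311 ± 35.9 in cKO (n = 3 each, exact permutation p = 0.1, two-sided). Of 7189 repeats within 3 kb upstream of a gene start and outside exons 25.9% rose, against 3.2% of 22618 in exons, 5.6% of 22690 in introns, 6.5% of 3018 within 5 kb downstream of a gene and 7.4% of 7886 elsewhere. Without cKO replicate 1 the repeats that rose numbered 2498 and those that fell 184, and the falls were 130 without WT replicate 2, 256 without WT replicate 3, 189 without cKO replicate 2 and 233 without cKO replicate 3. The authors' deposited table marked 6442 repeats as up and 1494 as down, of which 4595 and 406 were also called here, with 0 in the opposite direction. These calls came from different tests. Repeat rows were named by position with no family, so families were not analysed here.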

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

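The scaling alternatives were chosen after the data were seen. The depth limit is the 2-read floor of the table. Simulated power for 1.5-fold changes was low, but it reflects the spread between libraries as well as depth. Few genes were changed in that simulation, so power in the data may differ. Mtrex fell in every alternative run, with log2 changes of -3.12 to -2.39. The counts of histone, snRNA, long noncoding and snoRNA genes, PROMPTs and ptRNAs that rose stayed within 1.5 times in all alternatives run for them. Gene-row median, upper-quartile and total scaling and all-row total scaling shifted genes by 0.41, 0.47, 0.58 and 0.39 and, by construction, lowered the falls of genes to 250, 149, 74 and 378, of ptRNA hosts to 12, 6, 2 and 21, of PROMPTs to 6, 6, 6 and 7, of ptRNAs to 3, 3, 2 and 3 and of repeats to 98, 79, 62 and 115. They took repeats that rose to 8016, 8692, 10186 and 7895, while all-row total scaling left 21 ptRNA hosts that rose and 1 list that moved up. The stricter adjusted p of 0.01 gave 698 genes that rose and 842 that fell, 7 PROMPTs and 2 ptRNAs that fell, 17 hosts that rose and 353 that fell, and 2608 repeats that rose and 49 that fell; 2 PROMPTs and 1 ptRNA fell against gene and host. A log2 change over 1 left 992 genes and 171 hosts that fell. With only replicates 1 and 2, 1185 genes, 353 hosts, 3 ptRNAs and 120 repeats fell. With a term for replicate 3, 709 repeats fell. Of camera's 5 lists down and 2 up, 0 and 0 passed with an estimated correlation. The fry test gave 9 down and 0 up, with no list passing fry with gene-row median scaling (smallest adjusted p = 0.183). Unlike camera, fry tests change from 0 and not against other genes. The gene median was -0.45 with the deposited scaling, so fry's falls may follow that shift. Leaving out 1 library at a time gave 795 to 1233 genes that rose and 986 to 4155 that fell, 2810 to 3060 PROMPTs that rose and 17 to 36 that fell, 460 to 562 ptRNAs that rose and 4 to 9 that fell, 21 to 44 hosts that rose and 487 to 965 that fell, 2498 to 4724 repeats that rose and 130 to 422 that fell, 3 to 15 PROMPTs that fell against the gene and 1 to 2 ptRNAs against the host, 44 to 69 pseudogenes that rose, and 1 to 3 lists up and 4 to 8 down. The lowest gene counts came without cKO replicate 2 (795 rises) and WT replicate 2 (986 falls); the cause was not tested. Without cKO replicate 3 the macrophage list moved down (camera adjusted p = 0.0341, up to 0.655 with another library left out; adjusted p = 0.654 with an estimated correlation), and with gene-row total scaling Dnajb1 and Ppp1r15a stood at 0.00 and 0.02. Of 109 named genes, 207 verdicts under other scalings, 106 without 1 library and 23 under other settings lost the call, and 4 and 5 gained it under these last settings.

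Replicate numbers were not taken to pair the samples, since same-numbered libraries correlated at 0.26, -0.03 and 0.43 across gene rows, and 3 of 6 libraries correlated best with their own number. The replicate 3 pair correlated at 0.18 to 0.45 in all 5 feature types, so a feature shared by replicate 3 of both groups stays open. The replicate block gave 1436 genes that rose, 6054 that fell, 754 repeats that fell and 6 lists down, the Leydig list among them (camera adjusted p = 0.00471). The erythroid list stayed up (adjusted p = 1.56e-09). The estimated correlation was added to the blocked, replicate 3, gene-row median and left-out cKO replicate 3 fits after the data were seen, and with it no list passed in the blocked fit (adjusted p = 0.764 for both of these).

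A count test in edgeR with other factors, DESeq2, a surrogate variable from sva and term tests were planned and not run. In place of a count test, limma-voom was run on values divided by the step, and it called 1165 genes as rises and 4073 as falls. No terms were used here. A filter of at least 1 count removes no row of this table.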

Other observations

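Among other noncoding RNAs, Rn7sk, which binds the elongation factor P-TEFb, rose from 75.6 ± 25.0 to 422 ± 100 normalized counts (log2 change 2.49, SE 0.34, limma adjusted p = 0.000459), and the imprinted antisense transcript Kcnq1ot1 from 336 ± 87.3 to 1030 ± 356 (1.57, SE 0.29, limma adjusted p = 0.00345). Both were chosen after their values were seen, and both rose with gene-row median scaling too. Malat1 passed under neither scaling, with log2 changes of 0.02 (limma adjusted p = 0.966) and 0.43 with gene-row median scaling (limma adjusted p = 0.463).

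The tests of size factors, protein-coding rises, repeat locations, snoRNA locations and other splits for genes, PROMPTs, ptRNAs, hosts and repeats were chosen or described only after their results, or the results they bear on, were seen.

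Most gene calls were falls with the deposited scaling. Factors recomputed over all rows matched the deposited ones to within 0.00147%, whereas factors over gene rows alone differed by up to 20.5%, so the scale is set by rows that are mostly repeats. Such a scale holds the typical repeat near 0 (median log2 change 0.03) and genes below it (-0.45), which may account for many falls. A loss of mRNA per cell in the knockout stays open, since no RNA added in known amount was used here, as do the 250 falls that passed with gene-row median scaling.

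Among protein-coding genes other than histones, 331 rose. Reads from a neighbour's upstream transcript, counted without strand, could raise them. Of the 331, 152 (45.9%) overlapped the 3 kb upstream of another gene in the table, against 34.5% of the others (odds ratio 1.61, Fisher exact p = 2.45e-05, and 2.14 within bins of expression level, as the genes that rose had a median of 7.36 CPM against 22.2). Overlap was taken over the whole gene, introns included, and gene length was not matched, so some windows may meet no exon. Zbtb12 and Tssk6 are among the 152. Where a window does meet exons, a neighbour's transcript and the gene itself cannot be told apart without strand. The other 179, with Prr15l, Spo11, Neurog3 and Gdf15, have no such neighbour in the table. Direct overlap with other genes, and neighbours absent from the table, were not checked. A biological rise and reads of other RNAs both stay open for these 179.

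Repeats that rose lay upstream of genes more often than elsewhere. The share that rose outside genes and their windows was 7.4%, against 25.9% upstream, where 40.1% of risen repeats lay, so reads of upstream transcripts may account for that part. With gene-row median scaling the contrast was smaller, at 15.5% outside against 35.8% upstream. Introns and downstream windows did not carry the same excess: the odds ratio of rising there against elsewhere was 0.761 (Fisher exact p = 1.15e-07). Levels were not matched. The median normalized count was 13.3 in introns and 18.3 downstream, against 21.4 elsewhere, so fewer repeats may pass there. The 582 repeats that rose elsewhere (1219 with gene-row median scaling) stay open, with unannotated transcripts and the repeats' own transcription both untested.

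A hypothesis that hosts fall further where their ptRNA rose was not borne out. Hosts of 507 ptRNAs that rose had a median log2 change of -0.55, against -0.62 for 434 others, a difference of 0.07 in the other direction (permutation p = 0.0114, across genes, which are not independent). If host counts include ptRNA reads, that would bias the difference upward. A change of the whole gene would do so too, since the split used the ptRNA's own level and not its ratio to the host. The test therefore cannot exclude that such hosts fell further. A hypothesis that snoRNAs outside other genes rose more often was not settled: 3 of 7 outside and 9 of 34 inside a gene on the same strand rose (Fisher exact p = 0.398).

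Splits of the 6 libraries into groups of 3 number 10, too few for a share under 0.05. The real split was the 1 of 10 with the most calls for genes (5217, highest other 7), PROMPTs (3129, highest other 0), ptRNAs (576, highest other 0), hosts (1007, highest other 10), repeats (5108, highest other 0), and the ratios of ptRNA to host (632, highest other 0) and PROMPT to gene (3358, highest other 0). For lists, 7 of 10 splits gave at least the 7 of the real one, and the highest other gave 15, when WT replicate 1 stood with cKO replicates 1 and 2.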
